A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

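Genomic DNA of 10 diploid yeast isolates was hybridised to SNP microarrays, 1 array per isolate. Per the labels, the DNA of each isolate carried Cy5 and was mixed with Cy3-labelled DNA of the control diploid JSC24. The isolates descend from the strain background W303-1A crossed with YJM789, strains that differ at many single nucleotides, so that a probe for each allele reads whether a diploid still holds both.

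The deposited table gives 1 linear ratio of sample to control per probe and array, for 53664 probes. Every array's ratios average 1, a scaling present in the deposited values. The feature filter, the background correction and the genome build of the probe positions are not given in the sources used here. Of the probes, 219 had no value on any array. Each SNP carries up to 4 probes, whose names hold a chromosome, a position, the letter S or Y and a strand letter. The labels do not define S and Y, so the alleles are called the S allele and the Y allele, and the plan to name the W303-1A and YJM789 alleles was carried out on these letters. Positions are printed as in the deposited table, and no gene was placed on them because no build is named.

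Columns were matched to isolates through the strain in the sample source. That strain reads MD891 or MD892 with the zygote number where the titles read MD893-1 or MD893-2 cross, and the grouping follows the titles. The groups were 4 zygotes of the MD893-1 cross, 2 zygotes of the MD893-2 cross, 2 isolates (A and B) of HK10 and 2 isolates (A and B) of HK12. The labels call the zygotes independent. Isolates A and B of an HK name share that name and may descend from 1 culture, so tests are given over isolates and over names, and p-values over isolates measure in part the spread within a name.

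Ratios were taken to log2 and centred on each array's median, with no loess or quantile step. For each of the 13461 SNPs with both alleles on the array, d was the mean log2 ratio of the S probes minus that of the Y probes, and s was the mean of both alleles. Each array's d was then centred on its median over SNPs, and its s on its median over heterozygous SNPs. A hidden Markov model with heterozygous, S homozygous and Y homozygous states ran along each chromosome. Its emissions were Student t densities with 4 degrees of freedom, centred at 0 with the array's own noise (at least 0.1) for the heterozygous state and at 3 and -3 with a scale of 0.8 for the homozygous states. The probability of a state change per SNP was 0.0001. A loss of heterozygosity (LOH) tract needed 5 SNPs, and its ends were put midway between its outermost SNP and the next SNP. A tract that reached the last measured SNP of an arm was terminal and any other was interstitial. The main counts left out tracts found in all isolates of at least 1 cross, with both ends within 3 SNPs. Copy number states of s used the same kind of model with levels 0.4 above and below 0, a minimum of 10 SNPs, and 80% of a chromosome's SNPs for a whole-chromosome call.

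Counts of events, the percent of the assayed 11559 kb in LOH and copy number calls were compared with exact two-sided permutation tests. Direction was compared with an exact sign-flip test over the 6 zygotes and the 2 HK names. Correlations over the 16 chromosomes used 100000 permutations, and breakpoint positions were compared with 10000 circular shifts along the SNP map. The median spacing of SNPs was 368 bp, which limits how short a tract can be seen, and the number of arrays limits the precision of every comparison. The calling of tracts was tested on simulated data made from each array's heterozygous SNPs, drawn independently. Homozygous values came from SNPs that the same model had called homozygous. Of 200 tracts of 5 SNPs planted over the 10 arrays, 98% were recovered, and of 200 tracts of 7 SNPs, 100%. Tracts were planted on measured SNPs only, so these shares do not cover tracts missed through probes without a value. A simulated extra copy of 1 homolog, which raised s by 0.26, was called in 96 of 96 chromosomes of the zygote arrays. The noise of d was 0.126 to 0.242 across arrays.

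The tests, the groups, the alternatives and the rule for named events were chosen before the data were examined. Alternatives that also left out tracts found in at least 2 zygotes, counted tracts of either state under 10 kb apart as 1, gave 1 value per HK name for the LOH share, or removed a curve (a quadratic in the logarithm of chromosome length) were added after seeing the data. The rule named every whole-chromosome copy number call, the 3 largest LOH tracts of each isolate, every tract over 100 kb found in isolates A and B of a name, and every region in LOH in at least 4 independent isolates. Further tracts named below were chosen after their values were seen. The planned allele states of named genes and the planned overlap of breakpoints with Ty elements, tRNA genes, replication origins, centromeres and ribosomal protein genes were not analysed here, since they need the build of the positions. Of the planned features at breakpoints, the distance to the end of the SNP map was analysed. Tract lengths were described and not tested between groups. The planned check for isolates of mixed genotype compared d between tracts. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.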

Results

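The series asked how cleavage by RNase H2, the enzyme that cuts DNA at embedded ribonucleotides, relates to genome instability in Saccharomyces cerevisiae. SNP microarrays measured both alleles along the 16 chromosomes of 10 diploid isolates. Of these, 6 were independent zygotes of crosses of MD893-1 (4 zygotes) or MD893-2 (2 zygotes), all with the same second parent, LSY3454-2. The other 4 were purified isolates named HK10 A, HK10 B, HK12 A and HK12 B. Each array gave d at 12324 to 13377 SNPs, where d is the log2 ratio of the S allele's probes minus that of the Y allele's probes. A heterozygous SNP has d near 0, and LOH leaves 1 allele and moves d up (S homozygous) or down (Y homozygous). The genotypes of the HK strains and of the crossed parents were not given in the labels and are not assumed here.

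The share of probes without a value was 0.857% to 3.99% in the MD893-1 zygotes, 10.1% to 10.5% in the MD893-2 zygotes, 5.53% and 5.94% in HK10 A and B, and 7.47% and 6.32% in HK12 A and B. The HK arrays thus lay between the arrays of the 2 crosses. The noise of d was 0.143 to 0.163 on the HK arrays and 0.126 to 0.242 on the zygote arrays. Zygote 1 of the MD893-2 cross (0.161) and zygote 1 of the MD893-1 cross (0.167) had noise close to that of the HK arrays and 0 counted LOH tracts each.

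The zygotes of both crosses were heterozygous along almost their whole genome, whereas the HK isolates had long stretches of LOH, on chromosomes IV, X, XII and XVI in HK10, on IV in HK12 A and B, and on XII in HK12 B. HK10 A and HK10 B each carried 14 LOH tracts, HK12 A carried 8 and HK12 B carried 9. Of the 6 zygotes, 4 had no counted tract, and zygote 2 of each cross had 1 tract of 5 SNPs on chromosome V. That tract was a model call at which the S allele was not lost. The HK isolates averaged 11.25 ± 3.20 tracts (SD, n = 4) and the zygotes 0.333 ± 0.516 (SD, n = 6), a difference of 10.9 that was larger than the spread within either set. The exact two-sided permutation test gave p = 0.00952, the smallest p that the 210 splits of 4 against 6 isolates can give. With 1 value per HK name the difference was also 10.9 and the exact two-sided p was 0.0714, the smallest that 2 names against 6 zygotes allow. With a minimum of 10 SNPs per tract the difference was 6.75, with the same p over isolates. The 2 sets differ at once in strain, in origin (purified isolates against zygotes) and in array signal along chromosome length. This comparison cannot tell these apart, and it gives no rate of LOH.

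**Figure D1:**
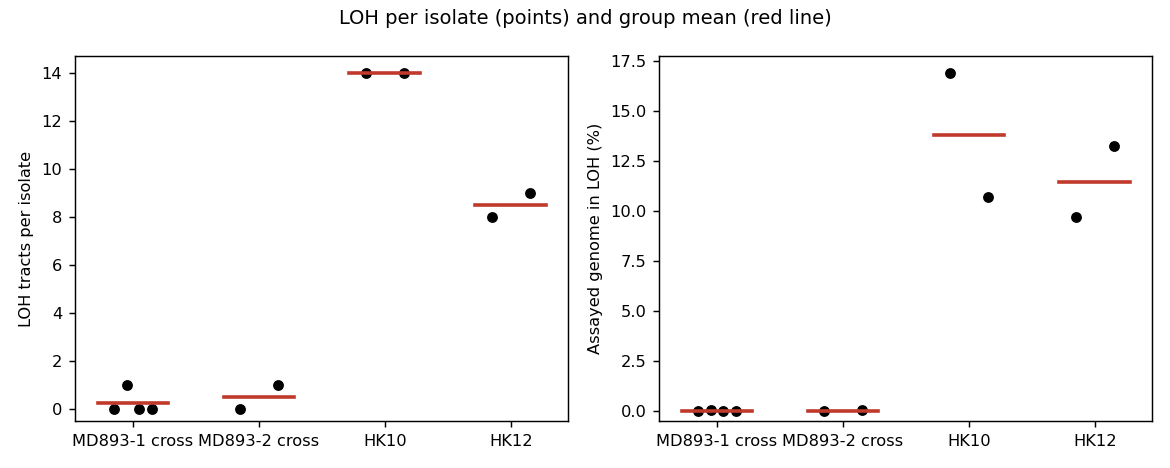
Counted LOH tracts per isolate (left) and percent of the assayed genome in LOH (right) for the 4 groups, with a point per isolate and a red line at the group mean. The 4 HK isolates lie at 8 to 14 tracts and the 6 zygotes at 0 or 1.

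LOH covered 16.9% of the assayed genome in HK10 A, 10.7% in HK10 B, 9.69% in HK12 A and 13.2% in HK12 B. In the zygotes the calls covered 0.0264% in each zygote with the chromosome V tract and 0% in the other zygotes. At that tract the S allele was not lost, at 0.03 and 0.08 on the log2 scale against heterozygous SNPs of the same chromosome. With that tract left out, the share was 0% in all 6 zygotes. The mean was 12.6% ± 3.21 (SD, n = 4) in the HK isolates and 0.0088% ± 0.0136 (SD, n = 6) in the zygotes, with an exact two-sided permutation p = 0.00952. With 1 value per HK name the exact two-sided p was 0.0714.

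The largest tracts reached the right ends of chromosomes IV and XII. In HK12 A and HK12 B the S allele was homozygous on chromosome IV from 458195 to the last SNP at 1515286, a terminal tract of 1058 kb. In HK10 A the S allele was homozygous on chromosome IV from 726278 to 1515286, over 789 kb and 596 SNPs. In HK10 B the tract to that end was shorter, from 1441463 to 1515286, over 75.5 kb and 111 SNPs. The stretch of chromosome IV from 1441463 to 1515286 was thus S homozygous in all 4 HK isolates, which stand for 2 names. A second stretch, on chromosome XVI from 110046 to 114409, was Y homozygous in all 4. On chromosome XII, which carries the ribosomal RNA gene repeats, the Y allele was homozygous in HK10 A from 342522 to 1058884 (717 kb) and in HK10 B from 343223 to the same last SNP (717 kb). In HK12 B the opposite allele, S, was homozygous on chromosome XII from 665226 to 1058884, over 397 kb and 659 SNPs, and HK12 A was heterozygous there.

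**Figure D2:**
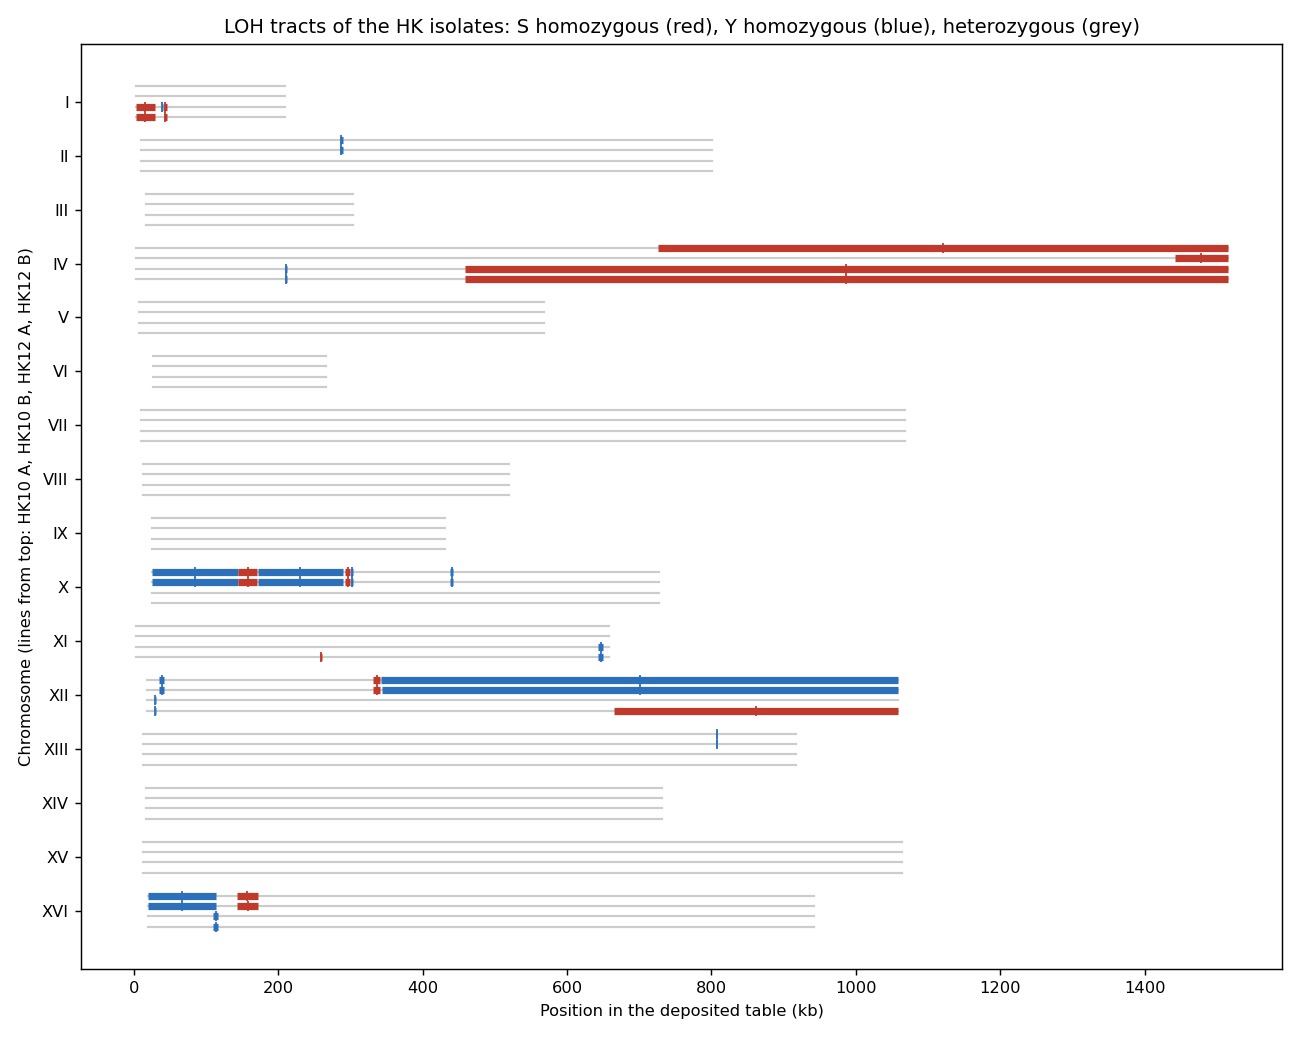
Map of the 16 chromosomes (position in kb) with a line for each HK isolate, S homozygous tracts in red, Y homozygous tracts in blue and heterozygous sequence in grey. Chromosome IV is S homozygous to its right end in all 4 isolates, and the left part of chromosome X alternates between Y and S in HK10 A and B.

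Chromosome X of both HK10 isolates alternated between alleles. The Y allele was homozygous from the first measured SNP to 144725 (120 kb), the S allele from 144874 to 170063, the Y allele from 171341 to 289211 (120 kb), the S allele from 292292 to 299865 and the Y allele from 301002 to 304215. Chromosome XVI of HK10 A and B was Y homozygous from 19454 to 114409 (95.3 kb). An S homozygous tract that began at 142517 in HK10 A and at 143229 in HK10 B ended at 172113 in both. Next to the long Y tract of chromosome XII, both HK10 isolates were S homozygous from 331220 to 340994. In HK12 the next largest tracts were on chromosome I, where the S allele was homozygous at the left end over 27.1 kb in HK12 A and 27.0 kb in HK12 B. HK12 A and B were also Y homozygous on chromosome XI from 642427 to 650268 (9.46 kb).

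In the 13 tracts of over 50 SNPs, the retained allele rose by 0.66 ± 0.04 on the log2 scale (SD) against heterozygous SNPs of the same chromosome, a 1.58-fold rise, and the lost allele fell by 2.73 ± 0.16. The retained allele lay between 0.58 and 0.74 in all 13 tracts, so each long tract had a gain of 1 allele beside the loss of the other. Over all 45 counted tracts of the HK isolates the rise was 0.66 ± 0.08 (SD), with a lowest value of 0.43 in the chromosome XIII tract of HK10 B. The absolute median d was 2.56 to 3.74 over these 45 tracts, and none lay at a level halfway to heterozygosity.

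Most tracts were shared by isolates A and B of a name, and no tract had the same ends in both names. Of the 14 tracts of HK10 A, 13 were found in HK10 B with the same allele and both ends within 3 SNPs (92.9%, exact 95% interval 66.1% to 99.8%). Of the 8 tracts of HK12 A, 7 were found in HK12 B (87.5%, exact 95% interval 47.3% to 99.7%), and of the 9 tracts of HK12 B, 7 were found in HK12 A (77.8%). These intervals treat tracts as independent, although several abut, and measure no spread between isolates, as each name has 1 pair. By length the tracts matched at both ends made up 59.6% of the LOH of HK10 A, 93.9% of that of HK10 B, 99.8% of that of HK12 A and 73.0% of that of HK12 B. The chromosome IV tract of HK10 B had no match by this rule, but HK10 A was S homozygous there too. HK10 A had a median d of 3.29 and 0 heterozygous SNPs of 110 over it. Over the 8 ordered pairs of HK isolates of different names, 0 tracts matched in both ends. By 50% reciprocal overlap, 1 tract matched in each of 4 of these pairs, those of HK10 A with HK12 A and B, through their long S tracts of chromosome IV. The tracts that differed within HK10 were the 789 kb and 75.5 kb tracts of chromosome IV. Over the 507 SNPs from 726278 to 1438183, HK10 A had a median d of 3.34 and HK10 B one of 0.05. Over the 674 SNPs of the chromosome XII tract that HK12 B had, its median d was 3.07 and that of HK12 A was -0.04. HK12 B also had a 5-SNP S tract on chromosome XI from 257395 to 259919, where HK12 A was heterozygous. The 5-SNP Y tract of HK12 A on chromosome I from 38493 to 40369 was not counted in HK12 B, which had a median d of -2.92 there with 0 heterozygous SNPs but only 4 SNPs measured, under the minimum of 5.

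**Figure D3:**
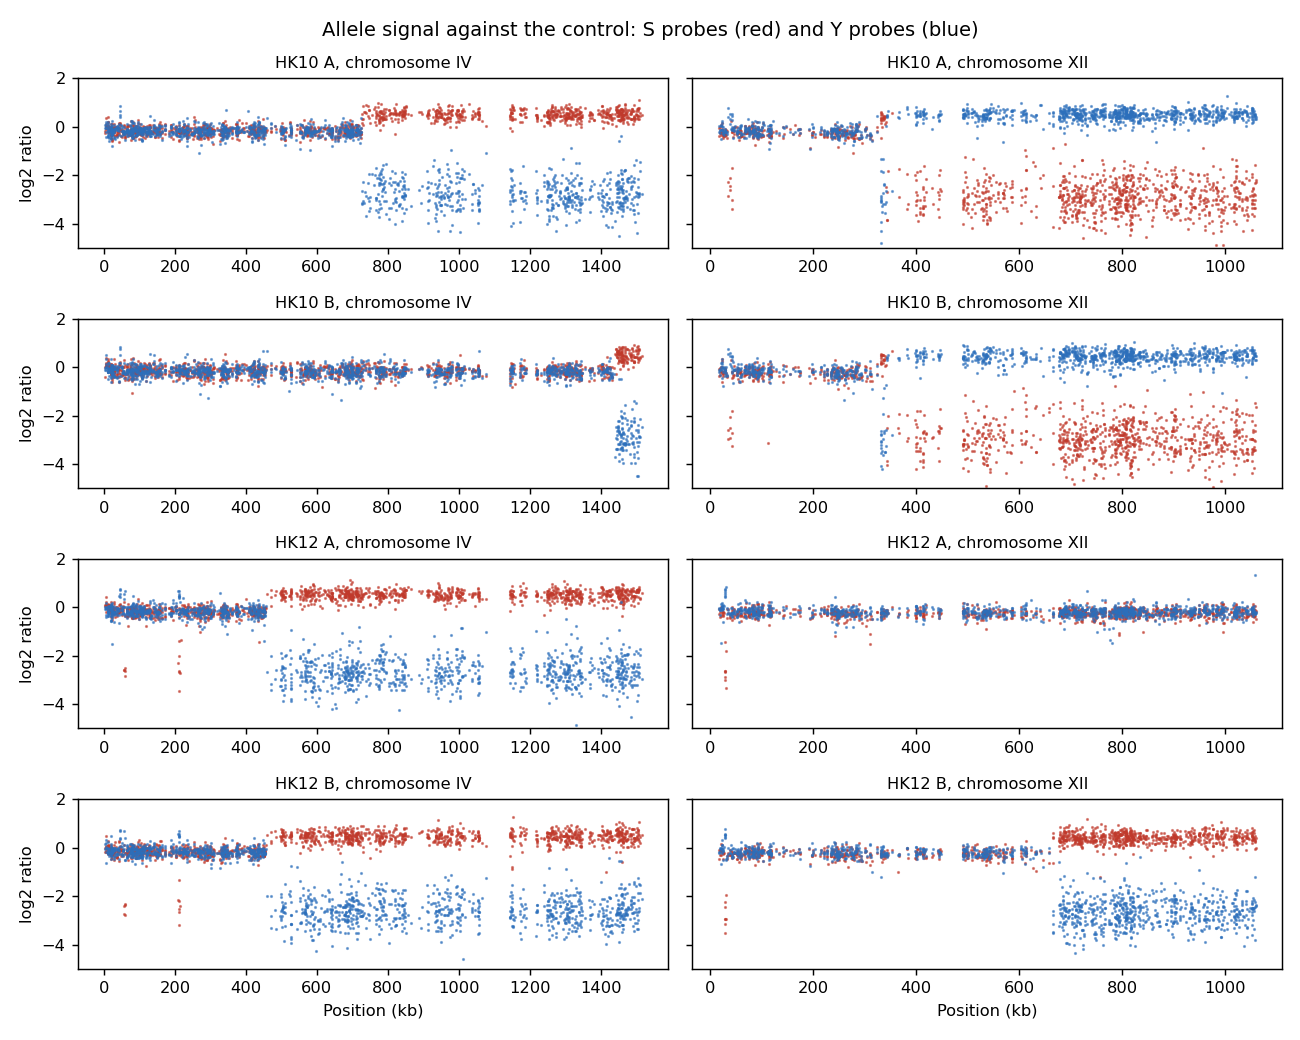
Log2 ratio to the control of the S probes (red) and Y probes (blue) per SNP along chromosomes IV (left) and XII (right) of the 4 HK isolates, position in kb. The alleles part at 726278 on chromosome IV in HK10 A and at 1441463 in HK10 B. On chromosome XII they part from 665226 to the right end in HK12 B but not in HK12 A.

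No difference in LOH between the crosses was detectable. The MD893-1 zygotes had 0.25 ± 0.50 tracts (SD, n = 4) and the MD893-2 zygotes 0.5 ± 0.707 (SD, n = 2), a difference of -0.25 with an exact two-sided permutation p of 1. The 15 splits of 4 against 2 zygotes allow no p under 0.133, so this design could not have reached the threshold. Both counted tracts were the Y call on chromosome V from 31251 to 33770. At that locus the Y allele was raised by a median of 1.47 over all 10 isolates while the S allele stood at 0.08, unlike in the long tracts of the HK isolates, where 1 allele was lost. No other tract was counted in the 6 zygotes.

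A tract on chromosome II was present in every isolate. It was called Y homozygous from 469650 to 474265 over 9 SNPs. The S allele stood at a median of -3.23 and the Y allele at -0.20 on the log2 scale over the 10 isolates. The Y allele ranged from -0.34 to -0.11 and did not rise as the retained allele did in the long tracts. The S signal was thus lost there without a gain of the Y allele, so homozygosity for Y is not shown. A second shared tract, on chromosome XV from 370120 to 371629, was called S homozygous in 6 of the 10 isolates, among them both MD893-2 zygotes. The S allele stood at a median of 1.43 and the Y allele at -0.70 over the 10 isolates. The Y allele did not fall as the lost allele did in the long tracts, so homozygosity for S is not shown. The 6 isolates were those with 5 SNPs measured there, and d lay above 0 in all 10. The tracts of chromosomes II and XV were left out of the counts above.

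Counting tracts shared by A and B once, the HK isolates had 17 interstitial tracts with a median length of 8.60 kb (2.65 kb to 120 kb) and 8 terminal tracts with a median of 259 kb (27.1 kb to 1058 kb). The chromosome IV tract of HK10 B, which lies within that of HK10 A, was counted as a separate tract. The interstitial median depended on the definition, as it was 14.4 kb with a minimum of 10 SNPs and 4.79 kb between the outermost SNPs of a tract. No whole chromosome was in LOH. Chromosome X held 6 tracts, XII held 5, IV held 4, and I and XVI held 3 each. Chromosomes III, VI, VII, VIII, IX, XIV and XV held none. Over the 16 chromosomes, the 27 tracts so counted, including the 2 zygote calls on chromosome V, had no relation to assayed length that passed the test. Pearson's r was 0.328 (permutation p = 0.218, two-sided) and Spearman's rho was 0.235 (permutation p = 0.376, two-sided), both with an adjusted p of 0.376 over these 2 relations. Without chromosomes I and IV, r was 0.315. These tracts may not all be separate events, as several on chromosomes I, X and XII abut. Counting tracts of either allele under 10 kb apart as 1 and leaving out the chromosome V calls, a choice made after seeing the data, gave 17 events with r = 0.533 (permutation p = 0.0346, two-sided) and rho = 0.399 (permutation p = 0.126, two-sided), adjusted to 0.0691 and 0.126 over these 2. Without chromosomes I and IV that r was 0.461 (permutation p = 0.0963, two-sided), so a relation to length is left undecided. The 42 breakpoints of the HK names lay a median of 146 kb from the nearer end of the SNP map, against 184 kb after circular shifts (one-sided permutation p = 0.226).

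No preferred allele in LOH passed the test. HK10 had on average 4 fewer S tracts than Y tracts and HK12 0.5 fewer, and the mean of S minus Y over the 8 zygotes and names was -0.81 (exact two-sided sign-flip p = 0.125, the smallest that the 4 nonzero values allow). By length the names went opposite ways, since LOH for the S allele covered 1.35% to 7.53% and for the Y allele 9.37% to 9.38% of the assayed genome in HK10. In HK12 the S allele covered 9.43% to 13.0% and the Y allele 0.234% to 0.256%. The sign of the direction depended on the minimum tract size, as it was 0.19 with a minimum of 10 SNPs. With a minimum of 3 SNPs it was -1.69 and had an exact two-sided sign-flip p of 0.0313, but 4 of its 6 nonzero values were zygotes whose only call was the chromosome V tract. Without the chromosome V calls at the main minimum it was -0.56 (exact two-sided p = 0.5).

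Signal over both alleles was raised on the shortest chromosomes of the HK isolates and on no chromosome of the zygotes. The model called a whole-chromosome gain of I, III, VI and IX in each of the 4 HK isolates and 0 whole-chromosome changes in the 6 zygotes (exact two-sided permutation p = 0.00952). The exact two-sided p was 0.0714 with 1 value per HK name. The mean s over the 4 HK isolates was 0.68 ± 0.03 (SD) for chromosome I, 0.62 ± 0.02 for VI, 0.46 ± 0.02 for III, which carries the mating-type locus, and 0.28 ± 0.01 for IX. In the zygotes the same chromosomes had means of -0.03, -0.01, -0.01 and -0.02 (n = 6). Chromosomes VIII (0.16 ± 0.01) and V (0.15 ± 0.01) lay between, and the lowest were IV (-0.15 ± 0.01) and XII (-0.20 ± 0.01).

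The levels in the HK isolates followed chromosome length. Pearson's r of s with assayed length was -0.89, -0.90, -0.89 and -0.89 in HK10 A, HK10 B, HK12 A and HK12 B. Spearman's rho was -0.976 to -0.979, each with a permutation p of 1e-05, the smallest that 100000 permutations give, and an adjusted p of 2.5e-05 over the 10 arrays. Without the 2 chromosomes farthest from the median length, r was -0.94 in all 4 HK isolates. In the zygotes r was 0.23 to 0.82. It passed the test in the 4 MD893-1 zygotes (adjusted permutation p of 0.00018, 0.000933, 0.023 and 0.0355 for r, though 0.063 for rho in zygote 4) and not in the 2 MD893-2 zygotes (adjusted permutation p of 0.383 and 0.0792). Without the 2 chromosomes farthest from the median length, r was 0.84, 0.79, 0.46 and 0.41 in the MD893-1 zygotes and -0.24 and 0.27 in the MD893-2 zygotes. The zygotes' s spanned at most 0.07 over the chromosomes, against 0.83 to 0.92 in the HK isolates. After a curve in length fitted to the other 15 chromosomes was removed, 0 whole-chromosome gains were called in any isolate, so the 4 calls are given here as signal levels. The curve would also absorb a gain common to the shortest chromosomes. Segments of changed copy number, 2 to 6 per HK isolate and 0 in each zygote, were likewise 0 after that removal, which was chosen after seeing the data.

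**Figure D4:**
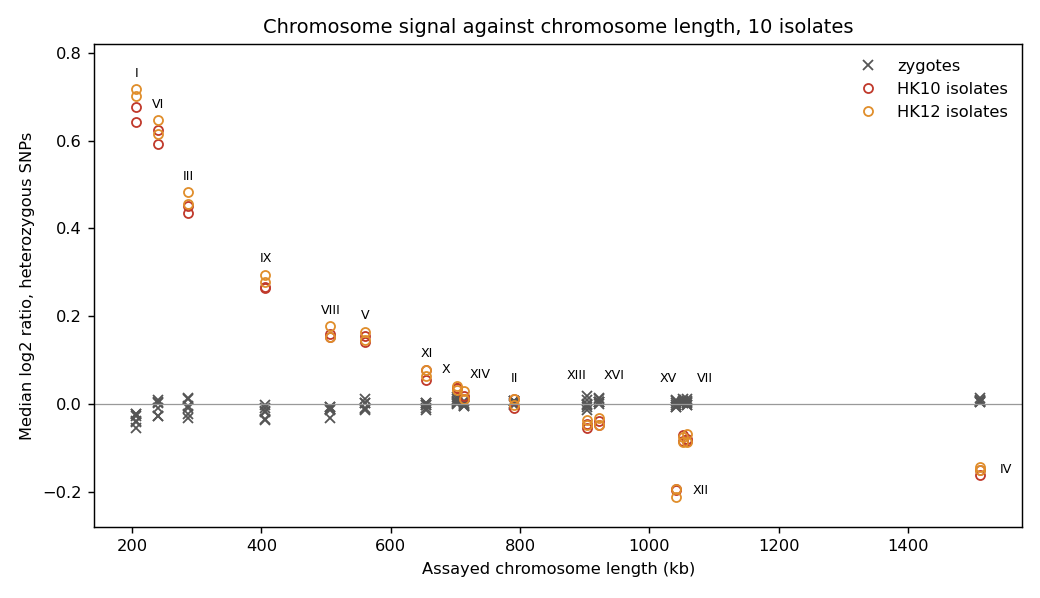
Median log2 ratio over both alleles at heterozygous SNPs of each chromosome against its assayed length in kb, with open circles for HK10 (red) and HK12 (orange) isolates and grey crosses for zygotes. The HK isolates run from about 0.68 on chromosome I to -0.15 on chromosome IV and -0.20 on chromosome XII, and the zygotes stay near 0.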

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

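All tests of explanations in this part were chosen after the result was seen.

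Among the 4 zygotes of the MD893-1 cross, 20 measures were checked for a zygote far from the other 3, and 4 stood out. The criterion is one that chance meets in about 1 of 20 groups of continuous values. It does not apply to the LOH measures, where any single call among 4 zygotes stands out. Zygote 2 had 1 LOH tract and 0.0264% of the assayed genome in LOH, against 0 in the other 3. Both values are the same chromosome V tract, weighed next. The median s of chromosome VIII was -0.00624 in zygote 1, against -0.0131 to -0.0121 in the others. The median s of chromosome XVI was 0.0117 in zygote 3, against 0.00376 to 0.0051 in the others.

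The chromosome V tract was called in 2 zygotes and in no HK isolate, and the chromosome XV tract in 5 zygotes and HK12 A, but d left 0 the same way at each locus in all 10 isolates (below 0 on V, above 0 on XV). Each tract was called only in the isolates with 5 SNPs measured at the locus, the minimum for a tract. A copy-neutral LOH tract is argued against, since the lower of the medians of the raised allele at the 2 loci was 1.43, above the highest rise of 0.738 seen for a doubled allele in the long tracts. An allele reduced or missing in the control DNA could raise the ratio in every array, and 18 of the 20 isolate and locus values lay above 0.738. The other allele stood at a median of 0.08 on V (S) and of -0.70 on XV (Y), and a missing allele by itself does not cover the lower level on XV. A change in the control DNA stays open as a candidate, because the control DNA was measured here on no array without an isolate. No biological explanation other than a copy-neutral LOH tract was tested.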

How the results depend on the processing

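The alternatives that removed a curve in length, gave 1 value per HK name for the share, counted tracts of either state under 10 kb apart as 1 or also left out tracts found in at least 2 zygotes were chosen after the results were seen. The excess of tracts in the HK isolates kept its direction under every alternative run, from 6.75 (minimum of 10 SNPs) to 13.1 (minimum of 3 SNPs) tracts per isolate. It was 10.9 with 1 value per HK name, where the exact two-sided permutation p rose to 0.0714, and 10 to 12 without each isolate in turn. The LOH share was 12.6 percentage points with 1 value per HK name, with the same exact p, and 11.2 to 13.6 without each isolate in turn. These p-values rose because fewer values leave fewer splits.

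The difference between the crosses, -0.25 tracts and -0.0066 percentage points, rests on the chromosome V call. It was made only in the 2 zygotes with 5 SNPs measured there. MD893-1 zygotes 1, 3 and 4 had a median d of -1.86, -1.89 and -1.81 on 4, 2 and 4 SNPs, and MD893-2 zygote 1 had -1.04 on 3. With tracts found in all isolates of a cross kept, the difference was -0.5 tracts and -0.0137 percentage points (exact two-sided permutation p = 0.933 and 0.267). The difference was 0.25 and 0.0066 with a minimum of 3 SNPs or a running median. It was 0 for both with a minimum of 10 SNPs or without the 10% most variable SNPs. The same held when tracts of at least 2 zygotes were also left out. Without each zygote in turn it ran from -0.75 to 0.25 tracts and from -0.0198 to 0.0066 percentage points, and was 0.25 and 0.0066 without MD893-2 zygote 2. Zygotes 1 and 2 of the crosses share only a number. With that number as a block, which leaves MD893-1 zygotes 3 and 4 without a partner, the paired difference was 0 for both. The deviations of same-numbered zygotes correlated at -0.24 over SNPs and those of differently numbered zygotes at 0.24. Taken over 2 zygotes of each cross, these correlations are mirror images and hold only 1 value.

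The whole-chromosome calls, 4 more per HK isolate, were 4 without each isolate in turn and 0 after a curve in length was removed. With 60% of a chromosome's SNPs for a call they were 4.25, as XII of HK12 B was then called lost. The share of its heterozygous SNPs in the loss state was 66.2% in HK12 B, 44.1% in HK10 A, 40.3% in HK10 B and 35.8% in HK12 A. The direction of LOH was -1.69 with a minimum of 3 SNPs (exact two-sided sign-flip p = 0.0313), 0.19 with a minimum of 10 SNPs, 86.5 kb by length, and -1 to -0.625 without each isolate in turn, and the cause was not tested. It was -0.56 when tracts of at least 2 zygotes were also left out (exact two-sided p = 0.5). The median interstitial length, 8.60 kb, was 7.05 kb with a minimum of 3 SNPs, 14.4 kb with 10 and 4.79 kb by inner SNPs only, and the terminal median was 257 kb to 259 kb. Sharing within names was the same under both other rules, and between names 50% reciprocal overlap matched 1 tract in 4 of 8 pairs. The relation of tracts to chromosome length had an r of 0.315 to 0.431 and stayed short of the threshold, except that r was 0.533 (permutation p = 0.0346, two-sided, 0.0691 adjusted) with tracts of either state joined and tracts of at least 2 zygotes left out, where the cause was not tested. Breakpoint intervals widened by 1 kb were not run, since no features were placed.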

Other observations

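All tests of explanations in this part were chosen after the result was seen.

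Tracts of opposite alleles lay side by side in both HK names. HK10 A and HK10 B each had 5 pairs of neighbouring tracts under 10 kb apart, 4 on chromosome X and 1 on chromosome XII, and all 5 pairs joined an S tract to a Y tract. On chromosome X the last Y SNP at 144725 and the first S SNP at 144874 were 0.149 kb apart. HK12 A had 2 such pairs on chromosome I, around its Y tract from 38493 to 40369. When tracts of either allele under 10 kb apart were counted as 1, HK10 A and B had 9 each, HK12 A had 6 and HK12 B had 9. Part of that gap rests on the chromosome I Y tract, which HK12 B showed on 4 SNPs (median d -2.92), under the minimum of 5.

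For the raised signal on chromosomes I, III, VI and IX of all 4 HK isolates, an extra copy of 1 homolog is argued against, as the alleles of these chromosomes differed by at most 0.174 where a doubled allele rose by at least 0.584. Whole extra copies of both homologs in all cells are argued against by 6 chromosomes (III, V, VIII, IX, X and XI) that lay between 0 and the level of a doubled allele. The margin of 3 SD used for this measured the spread over the HK isolates and not the uncertainty of the baseline. Of the 6, X (0.04) and XI (0.07) lay nearest to 0. Chromosomes I (0.68) and VI (0.62) lay near the level of a doubled allele (0.66). Extra copies in only part of the cells were not tested. A signal that depends on chromosome length may account for it, and a curve fitted to the other 15 chromosomes left a median of 0.0248 of a level of 0.537. Each fit included the other raised chromosomes, which are the shortest, so it would also absorb a gain common to them. The fit thus cannot tell the 2 apart. What made signal follow length stays open, as the labels tie no array to a batch. Missing probes do not set the HK arrays apart, since their share (5.53% to 7.47%) lay between those of the 2 crosses, whose s spanned at most 0.07.

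Chromosome XII, which carries the ribosomal RNA gene repeats, lay 0.12 log2 units below that curve in the HK isolates, at -0.12 ± 0.01 (SD, n = 4). Chromosomes VII and XV, of similar assayed length, lay at 0.02 each. The curve was fitted to assayed length, and the full length of chromosome XII with its repeats was not measured here. These values thus do not show whether XII departs from a trend in full length, which was not tested.

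The chromosome IV tract of HK10 A and the chromosome XII tract of HK12 B were not shared in full by the other isolate of the name. A missed call is argued against, since the other isolate had an absolute median d of at most 0.0501 over the parts it lacked. A mixture of genotypes in the isolate with the tract is argued against as well, since the lowest absolute median d of these tracts was 3.07, no lower than the 3.07 of the lowest shared tract. A mislabelled isolate would not leave the 13 and 7 shared tracts in place. Whether the difference arose after the isolates of a name parted was not tested, as these values do not show when a tract arose.

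Breakpoints of HK10 and HK12 were compared in case both names broke at the same places. Of the 25 breakpoints of HK10, 2 lay within 10 kb of an HK12 breakpoint, against a mean of 0.496 after circular shifts (one-sided permutation p = 0.154). The test leaves shared positions of breakage open, as the breakpoints are too few to decide.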
